A study of Danio rerio with 20 samples.

How the data were processed

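Bulk leukemia RNA from 11 zebrafish tumors was measured in 20 libraries of polyA RNA sequenced on an Illumina HiSeq, per the labels. The authors deposited a table of raw counts per gene, 1 column per library, with no normalization. The counts are whole numbers with totals that differ between libraries. Per the submitters' processing notes, STAR, Picard and featureCounts were used with the GRCz10 build. Their versions, the annotation release, read filters and the strand setting are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes cannot be told apart, and near-identical paralogs may share or lose reads, so values of paralogs and of immunoglobulin genes are uncertain. The table gives gene identifiers and no coordinates.

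The table held 32105 Ensembl genes, of which 5467 had no count in any library. A table of gene names gave a symbol to 26269 identifiers (81.82%). Identifiers without a symbol held 2.79% of the counts. Many symbols are human-style capitals that several paralogs share (4144 identifiers), so the identifier is printed beside such a symbol. Older symbols were matched through a RefSeq gene table of assembly GRCz12tu, from which only names were used. A list entry ending in a or b that had no symbol of its own was matched to every identifier with the shared capital symbol. Such members, for example those of MEF2C, FN1, FLI1 and SOCS3, may not be the paralogue written in the list. An identifier can also stand for different paralogues on different lists, as for FN1 and FLI1. Of 1128 list entries, 117 were not matched and 1 was left out because its match was another gene.

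Groups follow the self-renewal label of each sample. The unit of replication was the tumor: the libraries of a tumor, named by the same title apart from a final letter, were summed. This gave 8 high and 3 low tumors. The labels do not say whether tumors came from separate fish, or whether tumors 8.3 and 8.4.1.1.1, whose titles share a first number, are related, so the 8 high tumors may not be fully independent and p-values measure the spread between these tumors. Before summing, the 2 libraries of each tumor were compared by correlation and by a chi-square test of genes with at least 10 counts, to look for a library deposited more than once.

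Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, estimateDisp, glmQLFit and glmQLFTest (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2 scale, high over low, with standard errors from the F statistic. Log2 CPM values, counts scaled to the normalized library size, used a prior count of 2. Where a group had no count, the fold is a bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio has a 95% exact Poisson interval. Both use counts pooled over each group. Both cover counting error only. The median log2 fold change over all genes was 0.04 with TMM, 0.07 with RLE and 0.03 with upper-quartile factors.

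The 22 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01. List scores, the mean log2 CPM over a list, were tested by exact permutation. For each list the number of called members is given over all genes tested and adjusted over the list alone. Genes are named by this rule: among called genes with a symbol that is not a clone or locus name and a mean log2 CPM of at least 1 in the higher group, the 8 with the smallest p and the 6 further ones with the largest fold in each direction; then up to 4 called members of each list, or up to 2 members by p where none is called. Genes outside the rule are said to be chosen after their values were seen. The genes of the plot by tumor were chosen from the lists in the same way, apart from those the rule gives.

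The relation of T-cell and B-cell scores was planned over 11 tumors, with no pooled value where tumors form separate clusters. It is given within the 8 high tumors instead, which the plan does not name. With 8 tumors all orders were enumerated. Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors and filters, libraries as units with and without a block, thinned counts, stricter thresholds, fry and an estimated correlation, other scores, and leaving out tumors. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.

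The tests were checked on simulated counts with 200 changed genes, drawn for the real genes, library sizes and dispersions of the comparison of 8 high and 3 low tumors (15673 genes tested). The share recovered was 0% of genes changed 1.5-fold, 0% at 2-fold, 34% at 4-fold and 60% at 8-fold, with 0% false among 47 calls. A list shifted 2-fold was recovered (camera adjusted p = 3.50e-07), and 0 of 21 other lists were called. The simulated genes were drawn independently of each other, while the correlations estimated within the real lists ran from -0.019 to 0.825. This check therefore does not show how often correlated lists are called falsely. The simulation gave 47 calls against 1473 in the data. Adjustment with fewer calls sets a stricter limit on p, so the shares recovered may be lower than in the real comparison.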

Results

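Bulk polyA RNA from zebrafish leukemia cells was profiled to compare tumors whose cells had a high or a low capacity for self-renewal, that is, for starting a new leukemia. The fish were of the CG1 strain. The 20 libraries came from 11 tumors, of which 9 had 2 libraries and 2 had 1. The sample labels placed 8 tumors (14 libraries) in the high group and 3 tumors (6 libraries) in the low group. The series text instead counts 6 high and 5 low tumors, divided at 1% of cells able to start a leukemia. It does not say which tumors it means, so the groups here follow the sample labels. Total counts per library ran from 6015050 to 16951341. Summed per tumor, they ran from 11573276 in tumor 14.1.1.1 to 32466048 in tumor 8.3. The low tumors 9.2, 10.2 and 12.2 held 27432733, 28727277 and 16129049.

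The first comparison asked which genes differed between high and low tumors. The high tumors carried T-cell transcripts and the low tumors carried B-cell transcripts. Low tumor 12.2 also carried T-cell list transcripts, with a mean log2 CPM over the list of 4.41. The mean was 1.22 in low tumor 10.2 and -0.12 in low tumor 9.2. Of 16008 genes tested, 641 were higher and 832 lower in the high tumors in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 402 were higher and 500 lower by 4-fold or more. Every high tumor lay on one side of every low tumor in 1201 of the 1473 called genes (81.53%). Chance gives such a separation in 1.212% of genes, and it was seen in 11.85% of the genes tested. The first principal component held 34.85% of the variance and placed tumors 9.2, 10.2 and 12.2 at 143.8, 151.6 and 92.27, with the high tumors between -68.81 and -18.76. Low tumor 10.2 weighed most on the counts, which were 196 higher and 403 lower without it, and 385 higher and 629 lower without tumor 9.2. DESeq2 called 1754 higher and 1417 lower genes.

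Among genes with the smallest p-values, dachc (ENSDARG00000003142), a dachshund-family transcription cofactor, was higher in the high tumors by 4.34 ± 0.24 on the log2 scale (SE, 8 against 3 tumors, adjusted p = 3.23e-06). Its level was 36.03 ± 3.75 CPM (counts scaled to library size; SD, n = 8) in high and 1.76 ± 0.42 (SD, n = 3) in low tumors. The glycosyltransferase gene B3GNT5 (ENSDARG00000018971) was higher by 10.08 ± 0.72 (adjusted p = 1.45e-05). The lymphocyte integrin gene itgb7 (ENSDARG00000044318) was higher by 8.56 ± 0.68 (adjusted p = 3.40e-05). Also higher were marcksl1a (ENSDARG00000039034) by 4.68 ± 0.37, FAM78A (ENSDARG00000088222) by 4.71 ± 0.47, and the zinc finger gene HIVEP2 (ENSDARG00000039987) by 2.83 ± 0.25. The actin regulator VASP (ENSDARG00000099690) was higher by 2.56 ± 0.24 and the G-protein subunit gene GNG2 (ENSDARG00000056831) by 1.83 ± 0.18. These 8 genes were higher in 8 of 8 high tumors than in any low tumor, and all 8 were called whichever tumor was left out.

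In the opposite direction, PAX5 (ENSDARG00000037383), the transcription factor of B-cell commitment, fell by 10.13 ± 0.64 on the log2 scale from low to high tumors (adjusted p = 6.84e-06), from 141.7 ± 32.8 CPM (SD, n = 3) to 0.145 ± 0.168 CPM (SD, n = 8). The Ras exchange factor gene RASGRF2 (ENSDARG00000075054) had a log2 fold change of -5.46 ± 0.35. SWAP70 (ENSDARG00000051819), a B-cell signalling gene, had -6.60 ± 0.47, and the kinase gene tnk2b (ENSDARG00000104409) had -6.64 ± 0.51. The values were -12.11 ± 0.82 for sid1 (ENSDARG00000095540) and -8.74 ± 0.71 for CBFA2T2 (ENSDARG00000074337), a transcriptional corepressor (-11.10 and -7.57 without tumor 9.2). The phospholipase D family gene pld5 (ENSDARG00000063257) had 1 count over all high tumors and 1325 over the low tumors, a ratio of 2820 (95% exact Poisson interval 506 to 111400). GPR4 (ENSDARG00000079479), a proton-sensing receptor gene, had 3 counts against 2717, a ratio of 1927 (659.5 to 9345). These intervals cover counting error only. All 8 genes were lower in every high tumor than in any low tumor and stayed called whichever tumor was left out.

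The largest further fold changes included genes detected in only 1 group. RBFOX3 (ENSDARG00000010083), a gene of an RNA-binding protein of neurons, had 9087 counts in the high and 0 in the low tumors, at least 1423-fold higher in pooled counts against a floor of 3 counts over the low group. Its call was lost without tumor 10.2 (adjusted p = 0.0584). PLCB2 (ENSDARG00000090381), a phospholipase C gene, had 0 counts in the high and 538 in the low tumors, at least 382-fold lower in pooled counts against a floor of 3 counts over the high group. Pooled counts give deeper tumors more weight, so these bounds are not those of the mean CPM. lsr (ENSDARG00000099291), a tight-junction gene, was higher by 9.45 ± 1.40. DKK3 (ENSDARG00000103591), a dickkopf family gene, had 1 count in the low and 2419 in the high tumors, a ratio of 1137 (95% exact Poisson interval 204.0 to 44900). The synapse gene nlgn3b (ENSDARG00000062376) had 2 against 5428 counts, a ratio of 1275 (353.1 to 10530), and CAMTA1 (ENSDARG00000077428) had 1 against 2474, a ratio of 1163 (208.7 to 45920). DIRAS1 (ENSDARG00000028066), a small GTPase gene, was higher by 10.17 ± 2.81. These last 3 calls were lost without tumor 9.2 (adjusted p = 0.109, 0.117 and 0.113), 10.2 (0.135, 0.153 and 0.169) or 12.2 (0.0856, 0.103 and 0.120). The calls of CAMTA1 and DIRAS1 were also lost without tumor 15.2 (0.0522 and 0.0584), and that of DIRAS1 without 13.1.1 (0.0618) or 7.2.1 (0.0608).

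Of the largest falls, cd79b (ENSDARG00000104691), a B-cell receptor chain, had a log2 fold change of -9.69 ± 0.82 (adjusted p = 5.46e-05). The guidance molecule gene SEMA5A (ENSDARG00000058821) had -10.25 ± 1.27 (-6.85 without tumor 9.2; not called by limma-voom, adjusted p = 0.0543), RIMBP2 (ENSDARG00000001154) -9.65 ± 0.95 and the spectrin gene SPTBN4 (ENSDARG00000092624) -9.65 ± 0.80 (-8.42 without tumor 9.2). The value of s100s (ENSDARG00000036773), -10.66 ± 2.27, rested on tumor 9.2, which held a log2 CPM of 12.34 against -2.99 and -3.42 in tumors 10.2 and 12.2. Without tumor 9.2 its log2 fold change was 5.37, not called (adjusted p = 0.229). limma-voom did not call it either (-2.79, adjusted p = 0.657).

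T-cell genes were higher in the high tumors. Of 33 measured members of the T-cell marker list, 10 were higher and none lower over all genes tested in edgeR's test, from which all list counts below come unless another tool is named, and 23 were higher when adjusted over the list alone. DESeq2 called 24 higher and 1 lower, and limma-voom 22 higher. The members with the smallest p-values included cd99 (ENSDARG00000051975) at 6.77 ± 0.88, the thymocyte gene THEMIS (ENSDARG00000010619) at 6.10 ± 1.32, the chromatin organiser SATB1 (ENSDARG00000062621) at 5.26 ± 0.90 and GATA3 (ENSDARG00000016526), a T-lineage transcription factor, at 4.94 ± 1.01 on the log2 scale. Without tumor 12.2 the last 3 were 10.44, 7.47 and 7.13. The list passed limma's camera test (adjusted p = 3.20e-16). It did not pass with an estimated correlation (adjusted p = 0.281), and it passed limma's fry test (adjusted p = 0.00195). Several textbook T-cell genes, chosen after their values were seen, did not pass over all genes: lck, the kinase of the T-cell receptor, had 3.24 ± 1.19 (adjusted p = 0.114) and cd8a had 3.62 ± 1.39 (adjusted p = 0.1295). Their groups did not overlap. Over all genes, 6 members were higher without tumor 15.2, 6 without tumor 13.1.1 and 4 without tumor 10.2, where 15 were higher when adjusted over the list alone. Without tumor 14.1.1.1, 1 was lower over the list alone. Without tumor 12.2, 19 of 34 list members were higher over all genes and 28 when adjusted over the list alone. In that fit lck was higher by 6.97 ± 1.04 (adjusted p = 0.00195) and cd8a by 10.24 ± 0.52 (adjusted p = 1.97e-06).

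**Figure D1:**
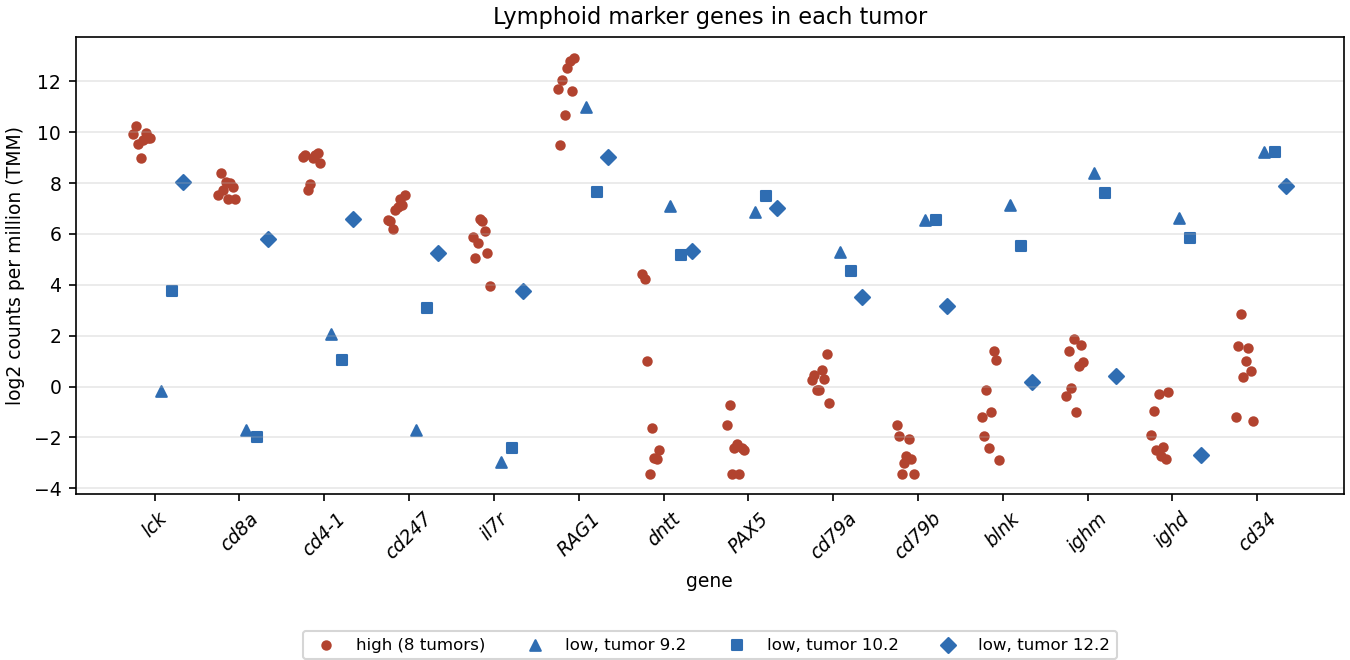
Expression of 14 lymphoid genes in each tumor, as log2 CPM on the vertical axis, with each of the 8 high tumors as a circle and the low tumors 9.2, 10.2 and 12.2 as a triangle, a square and a diamond. The low tumors 9.2 and 10.2 lie at the bottom for lck and cd8a and at the top for PAX5 and ighm, while tumor 12.2 lies near the high tumors for lck (8.05) and ighm (0.41) and with the other low tumors for PAX5 (7.03).

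B-cell genes were lower in the high tumors. Of 31 measured members of the B-cell marker list, 15 were lower and 1 was higher over all genes tested, and 16 were lower and 2 higher when adjusted over the list alone (4 higher without tumor 8.3, 3 without 8.4.1.1.1, 1 without 13.1.1 or 10.2). DESeq2 called 15 lower and 2 higher, and limma-voom 11 and 1. Besides PAX5, SWAP70 and cd79b, the B-cell receptor chain cd79a (ENSDARG00000037473) had a log2 fold change of -4.36 ± 0.43 (adjusted p = 0.000151). The immunoglobulin heavy chain gene ighm (ENSDARG00000096355), chosen after its values were seen, had -6.59 ± 0.97 (adjusted p = 0.00188). The exception was a MEF2C paralogue (ENSDARG00000029764), a transcription factor gene also on the oncogene list, higher by 1.80 ± 0.43 and not called without tumor 10.2 (adjusted p = 0.0968). The list passed the camera test (adjusted p = 3.77e-06), not with an estimated correlation (adjusted p = 0.281), and passed the fry test (adjusted p = 0.00180).

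Tumor 12.2 carried transcripts of both lineages. Its T-cell list score, the mean log2 CPM over the list, was 4.41, against 5.58 to 6.46 in the high tumors and -0.12 and 1.22 in tumors 9.2 and 10.2. Its B-cell list score was 3.02, against 0.60 to 2.21 in the high tumors and 4.12 and 4.42 in tumors 9.2 and 10.2. Its log2 CPM of PAX5 was 7.03, beside 6.86 and 7.48 in tumors 9.2 and 10.2, and its cd34 was 7.87, beside 9.22 and 9.21. Its ighm was 0.41, within the range of the high tumors (-1.01 to 1.88), while tumors 9.2 and 10.2 held 8.40 and 7.61. The adaptor gene blnk, which acts below the B-cell receptor and was chosen after its values were seen, stood at 0.19 in tumor 12.2. Tumors 9.2 and 10.2 held 7.14 and 5.54. Of 15 B-cell list genes that both 9.2 and 10.2 held above every high tumor, 12 were above every high tumor in 12.2 too. Tumor 10.2 also held some T-cell genes, chosen after their values were seen, near the level of 12.2. These were ZAP70 at 7.26 beside 7.55, TCF7 at 5.75 beside 5.92 and bcl11ba at 6.17 beside 6.36, while 9.2 held 4.42, 0.43 and -0.67. Others were far lower in 10.2 than in 12.2, such as cd8a at -1.97 beside 5.79. Both libraries of tumor 12.2 held both kinds, with T-cell scores of 4.54 and 4.26 and B-cell scores of 3.15 and 3.03. No labels give the lineage of a tumor, so these are levels only, and tumors were not regrouped by them.

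**Figure D2:**
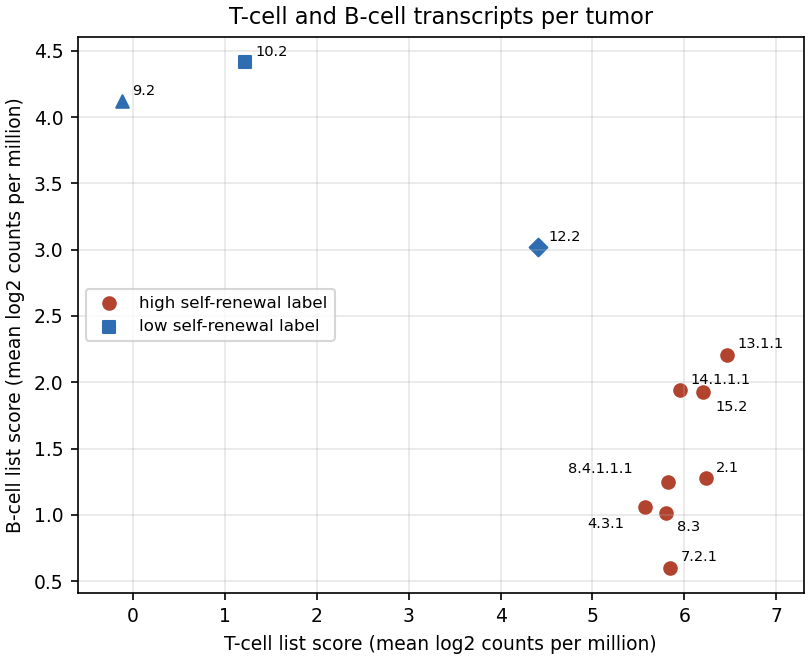
T-cell list score (horizontal axis) against B-cell list score (vertical axis) for each tumor, both as mean log2 CPM over the list's genes, with high tumors as circles and the low tumors 9.2, 10.2 and 12.2 as a triangle, a square and a diamond. The high tumors lie at T-cell scores from 5.58 to 6.46, tumors 9.2 and 10.2 at -0.12 and 1.22, and tumor 12.2 at 4.41.

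Of 15 measured genes of natural killer and cytotoxic cells, 2 were higher and none lower over all genes, and 3 were higher when adjusted over the list alone (DESeq2 6 higher, limma-voom 2). The called members, both also on the T-cell list, were GATA3 and RUNX3 (ENSDARG00000052826), a transcription factor of CD8 and cytotoxic cells, at 4.50 ± 1.02 on the log2 scale (5.86 without tumor 12.2). RUNX3 was not called without tumor 10.2 (adjusted p = 0.0974), where the counts were 1 and 1, and without tumor 12.2 they were 4 and 6 of 20. The list was not tested without the shared genes. As a list they passed camera (adjusted p = 0.000817), not with an estimated correlation (adjusted p = 0.281), and passed fry (adjusted p = 0.0124).

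Of 26 genes of lymphoid progenitors and antigen receptor recombination, 2 were higher and 2 lower, over all genes and when adjusted over the list alone (camera adjusted p = 0.637; DESeq2 4 and 2, limma-voom 3 and 3). Over all genes none was higher without tumor 8.4.1.1.1, 13.1.1, 7.2.1 or 10.2. Adjusted over the list alone, 5 were higher and 3 lower without 9.2, 3 and 2 without 14.1.1.1 or 12.2, and 0 and 2 without 10.2. The E-protein gene TCF12 (ENSDARG00000004714) had -3.59 ± 0.64, and a paralogue of the chemokine receptor gene CXCR4 (ENSDARG00000041959) had -2.84 ± 0.67, not called without tumor 9.2 (adjusted p = 0.0671) or 10.2 (0.0592). The nuclease gene DCLRE1C (ENSDARG00000045704) was higher by 1.74 ± 0.46 and tcf3b (ENSDARG00000099999), another E-protein gene, by 1.01 ± 0.27. DCLRE1C kept its call only without tumor 14.1.1.1, 4.3.1 or 8.3 (otherwise adjusted p = 0.0509 to 0.165). tcf3b lost its call without tumor 8.4.1.1.1, 13.1.1, 7.2.1, 9.2, 10.2 or 12.2 (adjusted p = 0.0583 to 0.163).

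Of 25 measured genes of stem and progenitor cells, 2 were higher and 3 lower over all genes, and 5 were higher and 6 lower when adjusted over the list alone (2 and 3 without tumor 14.1.1.1 or 2.1, 2 and 4 without 15.2 or 9.2, 3 and 5 without 10.2). DESeq2 called 5 higher and 7 lower, and limma-voom 1 and 5. The progenitor surface gene cd34 (ENSDARG00000095268) had a log2 fold change of -7.70 ± 0.76 (adjusted p = 0.000151), with 473.8 ± 207.9 CPM in low tumors (SD, n = 3) and 2.25 ± 2.22 CPM in high tumors (SD, n = 8). The chromatin gene HMGA2 (ENSDARG00000069912) had -4.65 ± 0.66 and LMO2 (ENSDARG00000095019), a hematopoietic cofactor that is also on the oncogene list, had -3.83 ± 0.71. The RNA-binding protein gene igf2bp1 (ENSDARG00000061478) was higher by 3.38 ± 0.79, not called without tumor 10.2 (adjusted p = 0.09998), as was FLI1 (ENSDARG00000054632), an ETS factor gene of blood and endothelium, by 4.74 ± 1.19, not called without tumor 9.2 (0.0886), 10.2 (0.1304) or 12.2 (0.0837). The list's median log2 fold change was 0.11 and its mean -0.31, so these differ in sign. It did not pass camera (adjusted p = 0.493) and passed fry in the lower direction (adjusted p = 0.0102).

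Of 19 leukemia transcription factor oncogenes, 1 was higher (the MEF2C paralogue above) and 2 were lower, LMO2 and a NOTCH1 paralogue (ENSDARG00000103554), over all genes and when adjusted over the list alone (camera adjusted p = 0.637; DESeq2 2 and 2, limma-voom 1 and 2). Without tumor 8.3, 7.2.1 or 12.2, 2 were higher over the list alone. Of 30 NOTCH pathway genes, 3 were higher and 2 lower, again in both counts (camera adjusted p = 0.405; DESeq2 5 and 4, limma-voom 2 and 3). Over the list alone, 5 were higher and 2 lower without tumor 9.2, 2 and 2 without 10.2, 2 and 0 without 12.2, and 3 and 3 without 14.1.1.1 or 4.3.1. The glycosyltransferase mfng (ENSDARG00000042925), which modifies NOTCH receptors, was higher by 2.69 ± 0.33 (adjusted p = 0.000663) and the coactivator MAML3 (ENSDARG00000079552) by 1.34 ± 0.24 (adjusted p = 0.00538). NRARP (ENSDARG00000091419), a NOTCH target gene chosen after its values were seen, was higher by 3.17 ± 0.81. It was not called without tumor 2.1 (adjusted p = 0.0511), 7.2.1 (0.0505), 9.2 (0.0710), 10.2 (0.146) or 12.2 (0.0874). The NOTCH1 paralogue had -3.23 ± 0.82 and the ligand gene dlc (ENSDARG00000002336) -2.82 ± 0.71. The paralogue kept its call only without tumor 8.4.1.1.1, 14.1.1.1, 8.3 or 7.2.1 (otherwise adjusted p = 0.0503 to 0.0852). The call of dlc was lost without tumor 14.1.1.1 (0.05001), 10.2 (0.0877) or 12.2 (0.120).

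No cell cycle gene was called. Of 97, none passed over all genes or when adjusted over the list alone in edgeR's test, 1 was lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The smallest p-values were those of mybl2a (ENSDARG00000095241), -0.64 ± 0.22 (adjusted p = 0.0993; -0.35 without tumor 10.2), and MCM10 (ENSDARG00000045815), 0.86 ± 0.42 (adjusted p = 0.223). The list did not pass camera (adjusted p = 0.248), whose direction was lower while the list's median (0.02) and mean (0.03) were above 0. It passed in the lower direction without tumor 4.3.1 (adjusted p = 0.0129), 7.2.1 (0.0116) or 9.2 (0.0410).

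Of 103 genes of ribosome biogenesis and MYC targets, 8 were lower and none higher over all genes, and 11 were lower when adjusted over the list alone (DESeq2 15 lower, limma-voom 10). They included 4 genes of ribosomal RNA processing or ribosome assembly, nop14 (ENSDARG00000098859) at -0.96 ± 0.20, rrp1 (ENSDARG00000103337) at -0.78 ± 0.16, wdr74 (ENSDARG00000061993) at -0.88 ± 0.20 and WDR75 (ENSDARG00000040730) at -0.73 ± 0.19. The list passed camera in the lower direction (adjusted p = 1.34e-05, median -0.32), not with an estimated correlation (adjusted p = 0.723), and did not pass fry (adjusted p = 0.123), and its score did not differ (exact permutation adjusted p = 0.25). Without tumor 10.2 no member was called (nop14, rrp1 and wdr74 had adjusted p = 0.0592, 0.0572 and 0.110). Nor were rrp1 without 12.2 (0.0516), wdr74 without 9.2 (0.0603), and WDR75 except without 8.4.1.1.1, 14.1.1.1 or 8.3 (0.0526 to 0.178). Over all genes, 2 were lower and 1 was higher without tumor 12.2. The number lower was 3 without 2.1, 15.2, 13.1.1, 7.2.1 or 9.2, 5 without 4.3.1 and 13 without 8.3. Adjusted over the list alone, 4 were lower without tumor 4.3.1, 2 without 2.1 or 15.2, and 0 without 13.1.1, 7.2.1, 9.2, 10.2 or 12.2.

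None of 76 ribosomal protein genes was called over all genes or when adjusted over the list alone in edgeR's test, 2 were higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. RPS9 (ENSDARG00000011405) had 0.64 ± 0.25 (adjusted p = 0.136) and RPL10A (ENSDARG00000042905) 0.60 ± 0.26 (adjusted p = 0.168). As a list they passed camera in the higher direction (adjusted p = 0.00406; 71 of 76 above 0, median 0.22), not with an estimated correlation (adjusted p = 0.843) and not without tumor 10.2 (adjusted p = 0.175).

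Of 36 measured glycolysis genes, 6 were higher and none lower over all genes in edgeR's test, and 6 were higher and 1 lower when adjusted over the list alone. DESeq2 called 8 higher and 1 lower, and limma-voom 3 and 1. Without tumor 8.3, 2 were lower over the list alone, and 0 without any other. They included the hexokinase gene HK1 (ENSDARG00000039452) at 1.82 ± 0.37, an aldolase paralogue ALDOC (ENSDARG00000019702) at 1.31 ± 0.29 and the lactate transporter gene SLC16A3 (ENSDARG00000045051) at 3.09 ± 0.75. Without tumor 10.2 none of these 3 was called (adjusted p = 0.0700, 0.0814 and 0.114), and no list member was in either count. ALDOC and SLC16A3 were not called without tumor 9.2 (0.0523 and 0.0803), nor SLC16A3 without 12.2 (0.0758). The glucose transporter gene slc2a3b (ENSDARG00000037861), higher by 2.99 ± 0.78 (4.125 without tumor 12.2), was not called without tumor 8.4.1.1.1, 15.2, 13.1.1, 7.2.1, 9.2 or 10.2 (0.0518 to 0.136). Over all genes, 3 members were higher without tumor 15.2, 13.1.1 or 7.2.1 and 1 without 9.2, where 1 was also higher when adjusted over the list alone. The list passed camera in the higher direction (adjusted p = 0.0127), not with an estimated correlation (adjusted p = 0.723) and not without tumor 9.2 (adjusted p = 0.101), and did not pass fry (adjusted p = 0.1535). Its score did not differ (exact permutation adjusted p = 0.107).

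Of 75 genes of oxidative phosphorylation, 3 were lower and none higher over all genes in edgeR's test and 1 was lower when adjusted over the list alone (camera adjusted p = 0.340). DESeq2 called 5 lower and 2 higher, and limma-voom 4 lower. COX4I2 (ENSDARG00000022509), an alternative cytochrome c oxidase subunit, had -7.32 ± 1.07 (-5.17 without tumor 9.2), and was called whichever tumor was left out. The complex I gene ndufv3 (ENSDARG00000090389) had -0.72 ± 0.19 and kept its call only without tumor 14.1.1.1, 8.3 or 9.2 (otherwise adjusted p = 0.0512 to 0.184). The cytochrome c oxidase gene cox6a1 (ENSDARG00000022438) had -0.72 ± 0.20 and kept its call only without 8.4.1.1.1, 8.3 or 2.1 (otherwise 0.0527 to 0.207). Over all genes, 5 were lower and 1 higher without tumor 8.3, and 1 was lower without 4.3.1, 15.2, 13.1.1, 7.2.1 or 10.2. Without 8.3, 9.2 or 12.2, 2 were lower over the list alone.

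Of 52 genes of PI3K, AKT and mTOR signalling, 4 were higher and 4 lower over all genes, and 9 were higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.637; DESeq2 11 and 8, limma-voom 6 and 4). The kinase gene akt1 (ENSDARG00000099657) had -2.39 ± 0.44 and the transcription factor FOXO1 (ENSDARG00000061549) -3.84 ± 0.73. The adaptor gene IRS2 (ENSDARG00000075282) had -3.35 ± 0.73, not called without tumor 9.2 (adjusted p = 0.0541). foxo3b (ENSDARG00000042904), another FOXO factor, was higher by 2.02 ± 0.47, not called without tumor 9.2 (0.0764) or 10.2 (0.109). The other called members, chosen after their values were seen, were foxo3a (ENSDARG00000023058) at 1.86 ± 0.48, the kinase genes GSK3B (ENSDARG00000017803) at 0.94 ± 0.26 and RPS6KA1 (ENSDARG00000033437) at 3.12 ± 0.89, and the mTOR subunit gene MLST8 (ENSDARG00000003167) at -0.79 ± 0.21. Of these, foxo3a was not called without 15.2 (0.0553), 9.2 (0.0793), 10.2 (0.158) or 12.2 (0.0775). GSK3B kept its call only without 4.3.1, 8.3 or 2.1 (otherwise 0.0509 to 0.202), RPS6KA1 only without 7.2.1 or 12.2 (0.0560 to 0.186), and MLST8 only without 8.4.1.1.1, 8.3, 13.1.1 or 7.2.1 (0.0502 to 0.126). Over all genes, 2 were higher without tumor 8.4.1.1.1, 9.2 or 12.2, 1 without 15.2 and 0 without 10.2, and 2 were lower without 9.2 and 8 without 8.3. Adjusted over the list alone, 0 were higher and 4 lower without 10.2, 4 and 4 without 12.2, and 5 lower without 13.1.1.

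Of 40 genes of the p53 response and apoptosis, 1 was higher over all genes in edgeR's test and none when adjusted over the list alone (camera adjusted p = 0.149). At an unadjusted p under 0.05, 9 were higher and 1 lower. DESeq2 called 8 higher and limma-voom 1 lower, and without tumor 14.1.1.1 edgeR's test called 1 higher and 1 lower. Without tumor 7.2.1 the list passed (adjusted p = 0.0376). The called gene, the pro-apoptotic bcl2l11 (ENSDARG00000079144), had 2.07 ± 0.59 and kept its call only without tumor 4.3.1 or 15.2 (otherwise adjusted p = 0.0513 to 0.133).

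Of 36 antigen presentation genes, 4 were lower and none higher, over all genes and when adjusted over the list alone (DESeq2 6 lower, limma-voom 3). The list score was 6.10 and 6.31 in tumors 10.2 and 12.2, 5.17 in tumor 9.2, and 4.07 to 5.69 in the high tumors. The invariant chain gene cd74b (ENSDARG00000036628) had -2.79 ± 0.67, not called without tumor 10.2 (adjusted p = 0.0905) or 12.2 (0.101), and the peptide transporter gene tap2t (ENSDARG00000033446) had -0.66 ± 0.15, not called without 9.2 (0.0685), 10.2 (0.0592) or 12.2 (0.0987). The other invariant chain gene, cd74a (ENSDARG00000009087), had -2.78 ± 0.74, not called without 8.4.1.1.1, 14.1.1.1, 2.1, 13.1.1, 10.2 or 12.2 (0.0571 to 0.169). The class II gene mhc2dab (ENSDARG00000079105) had -2.53 ± 0.69 and kept its call only without 4.3.1, 8.3, 7.2.1 or 9.2 (otherwise 0.0549 to 0.1503). The list passed camera in the lower direction (adjusted p = 0.00406), not with an estimated correlation (adjusted p = 0.723) and not without tumor 12.2 (adjusted p = 0.154), and did not pass fry (adjusted p = 0.252). Its score did not differ (exact permutation adjusted p = 0.2519). Over all genes, 2 were lower without tumor 8.4.1.1.1, 14.1.1.1, 2.1 or 13.1.1 and 0 without 10.2 or 12.2. Adjusted over the list alone, 0 were lower without 8.4.1.1.1, 2.1, 13.1.1, 10.2 or 12.2, and 8 without 4.3.1.

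Of 43 interferon response genes, 1 was higher and 2 lower over all genes, and 1 was higher and 4 lower when adjusted over the list alone (DESeq2 3 and 7, limma-voom 1 and 2). The antiviral gene mxe (ENSDARG00000014427) had -4.60 ± 1.07 and was not called without tumor 10.2 (-2.91, adjusted p = 0.201). The interferon-induced gene ifit8 (ENSDARG00000057173) had -4.93 ± 1.36 and kept its call only without tumor 8.3, 13.1.1 or 9.2 (otherwise 0.0530 to 0.4495, the latter with -2.30 without 10.2). The higher member was a paralogue of the cytokine signalling inhibitor SOCS3 (ENSDARG00000026611) at 1.98 ± 0.44, not called without tumor 9.2 (0.0663) or 10.2 (0.0577). The list passed camera in the lower direction (adjusted p = 0.00406), not with an estimated correlation (adjusted p = 0.734) and not without tumor 10.2 (adjusted p = 0.331), and did not pass fry (adjusted p = 0.316). Over all genes, 4 were lower without tumor 9.2, 1 without 8.4.1.1.1, 2.1, 15.2 or 12.2, and 0 without 10.2. Adjusted over the list alone, 11 were lower without 4.3.1, 9 without 9.2, 2 without 13.1.1, 1 without 8.4.1.1.1, 8.3, 2.1, 15.2 or 12.2, and 0 without 10.2.

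Of 48 immediate early and stress genes, 2 were higher and 1 lower over all genes, and 1 was higher when adjusted over the list alone (DESeq2 7 higher and 2 lower, limma-voom 5 and 1). They were SOCS3 (ENSDARG00000026611), which the interferon list also holds, the stress phosphatase subunit gene ppp1r15a (ENSDARG00000069135) at 1.498 ± 0.414 and the RNA decay gene ZFP36L1 (ENSDARG00000021443) at -2.22 ± 0.61. The call of ppp1r15a was lost without tumor 8.4.1.1.1, 14.1.1.1, 13.1.1, 7.2.1, 9.2 or 10.2 (adjusted p = 0.0557 to 0.186), and ZFP36L1 kept its call only without 13.1.1 or 7.2.1 (otherwise 0.0508 to 0.2245). In camera the list passed in the higher direction (adjusted p = 0.00465), not with an estimated correlation (adjusted p = 0.723), nor without tumor 9.2 (0.0944) or 10.2 (0.0966), and it did not pass fry (adjusted p = 0.324). Over all genes, 5 were higher without tumor 12.2 and 0 without 9.2 or 10.2. Over the list alone, 6 were higher without 12.2, 2 without 4.3.1, 15.2 or 7.2.1, 1 without 13.1.1 and 0 without any other, and 1 was lower without 13.1.1 or 7.2.1.

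Markers of other cells were measured because a bulk sample can hold them. Muscle, skin, gut and liver genes passed camera in the higher direction (adjusted p = 0.00142, not with an estimated correlation, adjusted p = 0.723, nor in fry, adjusted p = 0.1535), with 27 of 27 above 0. Of 66 genes matched, only these 27 passed the count filter. A gene near the floor can pass it through a few of the 8 high tumors more easily than through the 3 low ones. The filter may thus have favored folds above 0, though the list also passed camera without it. The score of this list did not differ (exact permutation adjusted p = 0.1556). It was low in all tumors, from -1.59 to 0.84 in the high and -2.04 to -1.20 in the low ones. High tumors 4.3.1 (-1.59) and 14.1.1.1 (-1.38) lay within the range of the low tumors. None was called over all genes or when adjusted over the list alone in edgeR's test, 11 were higher at an unadjusted p under 0.05, DESeq2 called 8 higher and limma-voom 0. The smallest p-values were those of the digestive enzyme genes prss59.1 (ENSDARG00000079274), with 231 counts in the high and 0 in the low tumors (adjusted p = 0.109), and CPA1 (ENSDARG00000021339) at 1.96 ± 0.73 (adjusted p = 0.120). The other lists did not pass camera. Of 44 myeloid genes, 1 was higher and 3 lower in both counts (adjusted p = 0.407; DESeq2 7 and 4, limma-voom 1 and 4). Over the list alone, 3 were higher without tumor 8.4.1.1.1, 2 without 4.3.1, 2.1, 7.2.1 or 12.2, and 0 without 9.2 or 10.2. The oxidase subunit gene NCF1 (ENSDARG00000033735) had -3.72 ± 0.69 and the metal transporter gene slc11a2 (ENSDARG00000024295) -0.86 ± 0.16. The cytokine gene il1b (ENSDARG00000098700) was higher by 3.56 ± 0.91, not called without tumor 9.2 (0.0963), 10.2 (0.117) or 12.2 (0.0557).

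Of 20 erythroid genes, 1 was lower in both counts (camera adjusted p = 0.155; median 0.02, mean -0.38, lower in the test). DESeq2 called 3 lower and limma-voom 1. Without tumor 8.3, 3 were lower in both counts, and without 10.2 it was 0 over all genes and 2 over the list alone. The called gene was a paralogue of the anion exchanger gene SLC4A1 (ENSDARG00000024560) at -6.24 ± 1.27, not called without tumor 10.2 (adjusted p = 0.0627) and not tested without tumor 14.1.1.1, where it fell below the count filter. Of 12 thrombocyte genes, 2 were lower over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.846; DESeq2 3 lower and 2 higher, limma-voom 1 lower). Over all genes, 3 were lower without tumor 15.2 and 0 without 8.4.1.1.1 or 2.1. Over the list alone, 1 was lower without 9.2, 10.2 or 12.2, and 2 were higher without 8.4.1.1.1, 8.3 or 7.2.1 and 1 without 14.1.1.1. The list's median was 1.78, and its direction was higher in camera and lower in fry. The integrin adaptor gene FERMT3 (ENSDARG00000030938) had -2.28 ± 0.58, not called without tumor 8.4.1.1.1 (0.0549), 2.1 (0.0587), 9.2 (0.173) or 10.2 (0.114). The fibronectin gene FN1 (ENSDARG00000019815) had -3.02 ± 0.81 and kept its call only without 15.2, 9.2 or 10.2 (otherwise 0.0504 to 0.7085, the latter with -0.59 without 12.2). Of 26 kidney, stromal and endothelial genes, 2 were higher and 2 lower over all genes, and 3 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.548; DESeq2 4 and 2, limma-voom 2 and 1). Over the list alone, 0 were higher without tumor 9.2 or 10.2, and 1 higher and 1 lower without 12.2. The genes called over all genes were FLI1 and FN1, both on another list too, the bicarbonate transporter gene SLC4A4 (ENSDARG00000044808) at -6.52 ± 0.98 (-3.41 without tumor 9.2, adjusted p = 0.0186) and the endothelial receptor gene lyve1b (ENSDARG00000062483) at 2.85 ± 0.71, not called without tumor 9.2 (0.0755), 10.2 (0.136) or 12.2 (0.0676).

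The list scores gave a value per tumor for each of the 22 lists. In an exact two-sided permutation test over all splits of the 11 tumors into 8 and 3, 4 scores differed, each at the smallest p the design allows (exact p = 0.00606, adjusted p = 0.0333). The T-cell score was 5.99 ± 0.29 in high (SD, n = 8) and 1.83 ± 2.33 in low tumors (SD, n = 3), and the B-cell score 1.41 ± 0.56 against 3.85 ± 0.73. The score of the stem and progenitor list was 2.58 ± 0.23 against 3.12 ± 0.09, although 15 of its 25 measured genes had a log2 fold change above 0. That of the natural killer and cytotoxic list was 1.73 ± 0.60 against -0.42 ± 1.08. No score passed when the median over genes replaced the mean, or without tumor 4.3.1, 8.3, 7.2.1, 9.2, 10.2 or 12.2. For lists at the smallest p alone to pass, at least 3 must reach it, or 4 with a high tumor and 10 with a low tumor left out.

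Across the 8 high tumors the T-cell and B-cell list scores gave Pearson's r = 0.709 (exact permutation p = 0.0509) and Spearman's rho = 0.738 (exact permutation p = 0.0458), two-sided, the only relation of this kind computed. Without the 2 tumors farthest from the median T-cell score, 13.1.1 and 2.1, r was 0.671 (exact permutation p = 0.142) and rho 0.543 (exact permutation p = 0.297) over 6 tumors, and neither passed. No value was computed over all 11 tumors, since high and low tumors form separate clusters. The plan did not name the relation within the 8 high tumors. The high tumors with the highest B-cell scores, 13.1.1, 14.1.1.1 and 15.2 (2.21, 1.94 and 1.93), also had the highest myeloid list scores. These were 3.60, 2.74 and 3.86, against at most 2.26 in the other high tumors, which was seen afterwards and not tested. In the high tumors PAX5, cd79b and cd37 were at most -0.73, -1.51 and -1.78. Other B-cell list members ranged more widely, such as SYK (-1.20 to 4.94) and fcer1gl (-0.12 to 4.33). A higher B-cell score here does not by itself mean more B cells.

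The 2 libraries of a tumor resembled each other more than any library of another tumor. Their correlations over log2 CPM ran from 0.981 in tumor 12.2 to 0.995 in tumor 8.3, and those between tumors from 0.735 to 0.934. The closest library was the partner in 100% of the 18 libraries that had one. No pair was within sampling noise: the chi-square divided by its degrees of freedom ran from 1.31 in tumor 9.2 to 31.3 in tumor 12.2. Tumor 12.2 also held the shallowest library, of 6015050 counts.

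**Figure D3:**
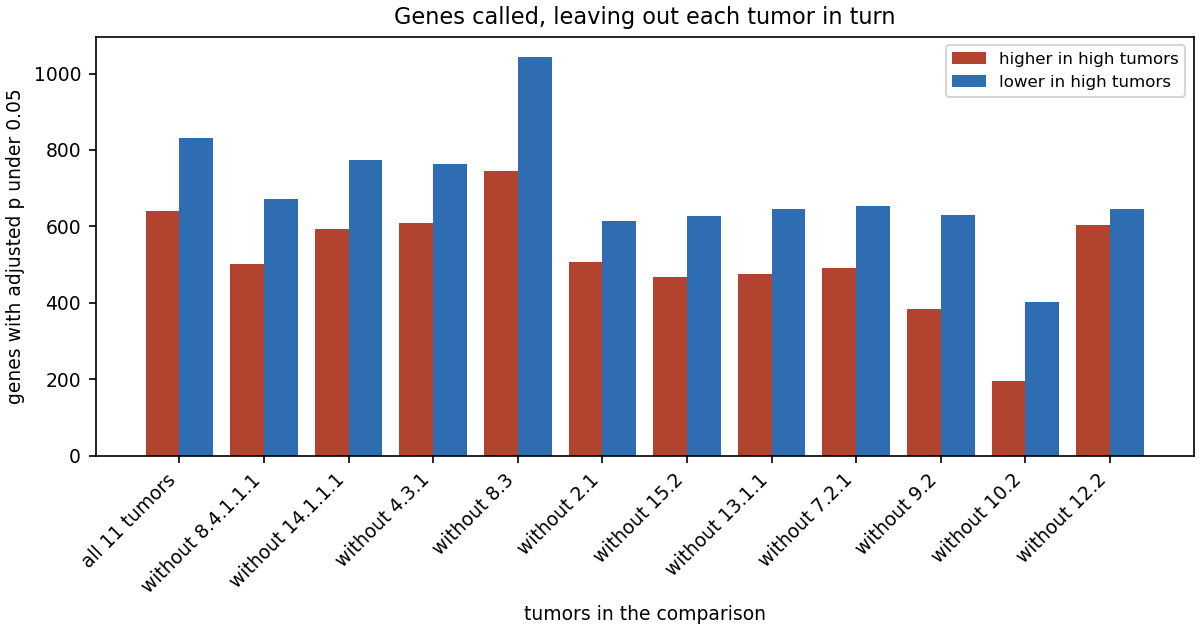
Number of genes with adjusted p under 0.05 (vertical axis, from 0) that were higher or lower in high than in low tumors, with all 11 tumors and with each tumor left out in turn. The counts were 641 and 832 with all tumors, and lowest without tumor 10.2, at 196 and 403.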

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

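In the 8 high tumors, 11 of 111 list scores, gene levels and totals had 1 tumor far from the others, by the gap to the nearest tumor divided by the whole range (limit 0.526). Chance gives about 1 in 20 groups where the values are independent and normally spread. Levels at the floor of -3.42, as for pld5, COX4I2 and SLC4A1, do not meet this, so the share here has no exact chance level. No explanation was tested for these values, which are given as log2 CPM.

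Tumor 7.2.1 had the lowest antigen presentation score, 4.07 against 5.06 to 5.69 (gap 0.609), and the lowest level of the class II gene mhc2dab, 2.93 against 5.67 to 7.83 (gap 0.560). It also held the only count of pld5 in the high group (gap 1). Tumor 13.1.1 had the lowest oxidative phosphorylation score, 5.43 against 5.67 to 5.86 (gap 0.549), and the highest level of COX4I2, -1.60 against -3.42 to -2.67 (gap 0.589), which is near the floor. Tumor 4.3.1 had the lowest RBFOX3 (ENSDARG00000010083), -2.48 against 3.48 to 6.74 (gap 0.647), and the lowest RASGRF2 (ENSDARG00000075054), 0.06 against 1.06 to 1.87 (gap 0.551). Tumor 14.1.1.1 had the lowest lsr, 0.36 against 5.88 to 7.22 (gap 0.804). It had the highest il1b, 5.19 against 2.01 to 3.10 (gap 0.658), tap2t, 5.84 against 5.27 to 5.53 (gap 0.548), and SLC4A1 (ENSDARG00000024560), -0.73 against -3.42 to -2.18 (gap 0.538). Tumor 14.1.1.1 has 1 library and the lowest total, 11573276 counts.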

How the results depend on the processing

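All alternatives were chosen before the data were examined, apart from taking the relation of T-cell and B-cell scores within the high tumors. The comparison rests on 3 low tumors. None of the simulated genes changed 2-fold or less was recovered, though some real genes with smaller changes were called. The simulation had fewer calls than the data, which made its adjustment stricter. In each alternative to the gene test, none of the genes called there and with all 11 tumors changed direction. Of the 1473 called genes, 97.83% were called with RLE, 96.67% with upper-quartile factors, 81.87% with limma-voom, 88.12% after thinning to equal depth, and 38.7%, 55.19% and 63.07% without tumor 10.2, 9.2 or 12.2.

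Against 641 higher and 832 lower genes, DESeq2 gave 1754 and 1417 (the cause was not tested). The 20 libraries taken as independent gave 2688 and 2272, since libraries of a tumor then count as replicates. With the replicate number as a replicate block they gave 2543 and 2199. These numbers showed no common pairing of the tumors. Over 36 pairs of tumors the correlation of the deviations had a median of -0.009. It ran from -0.329 to 0.316, and 7 were over 0.1, so effects shared by the libraries of some tumors stay open. A threshold of 0.01 gave 159 and 318, and a minimum fold of 2 gave 196 and 321, as stricter tests do. Leaving out 1 tumor gave 196 to 745 higher and 403 to 1044 lower genes. Leaving out 2 high tumors gave 347 to 777 and 460 to 993 over 28 pairs. Of the genes named, s100s reversed without tumor 9.2, the tumor that held nearly all its counts (log2 fold change -11.25 to 5.37 leaving out 1 tumor), and 35 of 82 called ones were called in every alternative.

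Against 6 higher and 4 lower lists, an estimated correlation gave 0 and 0. Only this setting differed, and the estimates for the lists that passed ran from 0.106 (glycolysis) to 0.825 (ribosomal proteins), above the preset 0.01. The passes of camera thus rest on the preset value. With fry, 2 and 2 lists passed (the cause was not tested), and 19 of 22 passed its test of change in either direction. Leaving out 1 tumor gave 4 to 7 higher and 3 to 5 lower lists, and the replicate block gave 6 and 4. Against 4 differing scores, the median over genes gave 0 and leaving out 1 tumor gave 0 to 4, where fewer splits raise the smallest p. The r of T-cell and B-cell scores within the high tumors was 0.772 with z-scores (exact permutation p = 0.0228), 0.04 with the median over genes (0.929), and 0.531 to 0.794 leaving out 1 tumor. The closest library was the partner in 100% of cases with Spearman's correlation and with the 1000 most variable genes.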

Other observations

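Genes described here were chosen after their values were seen. Among the high tumors, dntt, the polymerase that adds bases during antigen receptor recombination, stood at a log2 CPM of 4.43 in tumor 8.4.1.1.1, 4.24 in 14.1.1.1 and 1.02 in 4.3.1, and between -3.42 and -1.63 in the other 5. The low tumors held 5.16 to 7.11. The recombinase gene RAG1 was abundant in every tumor, from 7.63 in tumor 10.2 to 12.93 in tumor 7.2.1. The cell cycle score ran from 2.24 in tumor 8.3 to 5.08 in tumor 7.2.1 within the high group, which covers the 3.70 to 4.44 of the low tumors. The interferon score was 4.83 in tumor 10.2, 4.096 in 12.2 and 2.23 in 9.2, against 1.25 to 3.89 in the high tumors.

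The tests of the patterns below were chosen after the results were seen, except those of other splits and of library size, which were planned, and how the spread of T-cell genes in tumor 12.2 was read was changed after its value was seen. The first pattern is that genes differed between high and low tumors. The real split called 1473 genes, and the highest of the other splits drawn called 9. Only 1 of 100 splits, the real one, gave as many, which is the smallest share this draw could give. Each other split put high and low tumors in the same group, and 88 of them called 0 genes. The called genes thus followed the labels more than the other splits drawn. This test cannot tell whether the labels met the lineage transcripts by chance, since it compares splits of the same 11 tumors. A difference in library size as the whole cause is argued against by thinning, since 88.12% of the called genes were called at equal depth. Self-renewal label and lineage transcripts cannot be told apart, since 0 low tumors had T-cell and B-cell scores in the range of the high tumors, so whether the called genes go with self-renewal or with lineage stays open.

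The second pattern is that tumor 12.2 held T-cell and B-cell transcripts, with a T-cell list score of 4.41 against 1.22 in tumor 10.2 and -0.12 in 9.2. A swap of 1 of its libraries is argued against by their correlation of 0.981, when the highest with a library of another tumor was 0.911. Cells like tumors 9.2 and 10.2 in 1 proportion would lower alike the B-cell genes that the other cells lack. Over 15 B-cell list genes that 9.2 and 10.2 both hold above every high tumor, the SD of the log2 ratio was 2.92. It was at least 2.38 with any gene left out, against 1.18 between 9.2 and 10.2. The lowest ratios were those of ighd, ighm and blnk (-8.92, -7.60 and -6.15), and the SD without them together was not computed. The high tumors also held some of the 15, such as LYN (mean 5.78), so the SD alone does not decide. PAX5 and cd79b, with high means of -2.33 and -2.61, had ratios of -0.14 and -3.40. The SD of T-cell genes against the high tumors was 1.94, above their highest of 1.80. As first written, the reading was that such a value argues against 1 share of cells like the high tumors. The SD was 1.78 with 1 gene, cd99, left out, so such a share stays open. In tumor 12.2 cd99 was -1.32, near -1.54 and -0.88 in 9.2 and 10.2, against 3.33 to 6.54 in the high tumors. Other genes lay above the high mean, such as txk at 5.72 beside 2.73. Tumors 9.2 and 10.2 held txk at 4.41 and 5.71, and the high tumors reached 6.19, so its level leaves a mixture open. A candidate explanation is a leukemia that carries both programs, a hypothesis from 1 tumor that bulk RNA cannot separate from a mixture with B-lineage cells of another stage; data from single or sorted cells, which these samples lack, would be needed to test it.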
